A study of Mus musculus with 4 samples.

How the data were processed

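Droplet-based 3' single-cell RNA sequencing was run on cells dissociated with an adult brain dissociation kit from the uninjected side of the brain. The deposited matrices hold counts: whole numbers of UMIs per gene and barcode, not normalized, for 32285 genes in each of 4 libraries. Per the labels, the authors aligned reads to mm10 and counted with Cell Ranger 3.0.2 and analysed the cells with Seurat 2.3.4, whereas the headers of the deposited matrices name Cell Ranger 6.1.0. The difference was not resolved, and the annotation release is not stated. Positions in the text are those of GENCODE mouse release 21 (GRCm38), in which 32158 of the gene identifiers (99.6%) were found. The strain field of the labels differs between the 4 samples in its last digit while the description of the series names a single strain, and it was not used. Groups follow the labels (age and injection). No cell annotation was used, so cell classes were rebuilt, and a difference from the study may come from rebuilt names.

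Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs, which left 44503 of 46097. Doublet scores were computed per library with Scrublet (scanpy 1.11.5), and the highest-scoring cells were removed at a rate of 0.8% per 1000 barcodes, 4113 cells or 9.24%, leaving 40390. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were scaled (clipped at 10) and reduced to 30 principal components, and cells were clustered together on 15 neighbours with the Leiden method at resolution 1, without integration of the libraries (igraph 0.11.9, scikit-learn 1.9.0). Of 34 clusters, 31 were named from marker lists of 21 cell types, of which 19 names were used. A name needed a mean log2 ratio of the type's markers of at least 1, at least 3 of the type's markers detected and more of them than of any other type (or of cell cycle genes) among the cluster's 10 leading genes, unless no other type had any there. The clusters led by Klk6, by Hbb-bs with cell cycle genes, and by Hmga2 stayed without a name. The Klk6-led cluster had its best score for oligodendrocytes, but none of their markers among its leading genes. These held a marker of oligodendrocyte precursors (Enpp6) and a marker of fibroblasts (Apod).

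Within a class, UMIs were summed per library and divided by the class total (CPM). Ratios carry exact conditional 95% Poisson intervals, shares exact Clopper-Pearson intervals, and a count of 0 was replaced by 3 counts, which gives a bound. For the 26 fixed gene lists, the median log2 ratio was taken over members with at least 10 CPM in 1 or more libraries, with intervals from 1000 Poisson draws. The difference between the ages is the ratio of the tumour to sham ratios, and for a list it is the median over genes of that quantity. All intervals cover counting error only, and with 1 library per group no test was made. Named genes followed a rule set before the data were examined, as were the lists, markers and filters. It took genes with at least 100 UMIs over the libraries and at least 20 CPM in 1 of them. It left out mitochondrial, ribosomal protein, hemoglobin and Y-linked genes, Xist, and names of the form Gm with digits or ending in Rik. Genes with the same direction in both contrasts of a comparison (age, or tumour) were ranked by the smaller absolute log2 ratio, and the 10 highest and 10 lowest were taken in microglia-like cells, and 5 in each of the 4 next largest classes. By the difference between the ages, the 5 highest and 5 lowest were taken. The text names some of these genes and some members of the fixed lists, picked after their values were seen. The genes of the Hmga2-led cluster, and Avp and S100a9 as examples of genes that moved alike over most classes, were also chosen after their values were seen, as were the classes beyond the first 5.

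The procedure was tested on Poisson counts drawn from the mean microglia-like rates of the 4 libraries, over 5854 genes. Changes were set in the simulated old tumour library, which was compared with the simulated old sham. With 50 genes each set at a fold of 0.25, 2 and 4, 50 of 50 were called at each. At a fold of 1.5, 16 of 50 were called, and 0 of 5654 unchanged genes were called. The intervals held the true ratio for 95.0% of unchanged genes and for 88.0% of genes at a fold of 4. The draws hold counting error only and no variation between libraries, so this coverage and the lack of false calls were built in. They do not show how often unchanged genes would be called between the real libraries.

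Alternatives were no doublet removal, a stricter filter (1000 UMIs and 10% mitochondrial), Leiden resolution 2, median-centred scaling, the mean of each cell's CPM, thinning of each cell to 1000 UMIs, class totals without mitochondrial and ribosomal protein genes, and list members with at least 50 CPM or with 1 UMI in each library. Thinning left out 227, 172, 86 and 82 microglia-like cells in young sham, young tumour, old sham and old tumour. After the data had been examined, 3 more were added: microglia-like cells without the clusters led by Atf3 and Tnf, those of the clusters led by Tmem119 and P2ry12 only, and shares without the Hmga2-led cluster. Values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and drawn with matplotlib 3.10.9.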

Results

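Single-cell RNA profiles were measured in the brains of mice aged 8 or 93 weeks, 2 weeks after an injection of either 1000 CT2A-GFP-luc cells, a mouse glioma line, or saline (sham). The tissue came from the side of the brain opposite to the injection. Each of the 4 groups (young sham, young tumour, old sham, old tumour) was represented by 1 library, and the labels do not give the number of mice behind a library. There were therefore no replicates, no difference between groups was tested, and each interval is a 95% interval that covers counting error only. The libraries held 64464413 UMIs in 12070 barcodes (young sham), 75924528 in 12032 (young tumour), 62726818 in 10665 (old sham) and 76652484 in 11330 (old tumour). After filtering and doublet removal, 10571, 10461, 9529 and 9829 cells remained, with medians of 3920, 3773, 4731 and 4858 UMIs per cell. Their median mitochondrial percentages were 4.04, 3.75, 3.30 and 4.76, lowest in old sham, on which the age differences in sham rest. A value is called higher or lower only at a ratio of at least 1.5 in either direction.

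The first question was which cell types the tissue held at each age, with and without a tumour on the other side. T cell-like cells made up 0.501% of cells in young sham (0.376 to 0.655%, exact Clopper-Pearson), 3.67% in young tumour (3.32 to 4.05%), 1.15% in old sham (0.950 to 1.39%) and 1.87% in old tumour (1.61 to 2.16%). The tumour to sham ratio of this share was 7.32 in young mice (5.48 to 9.95) and 1.62 in old mice (1.27 to 2.07). Monocyte-like cells made up 0.814% of young sham, 6.19% of young tumour, 0.745% of old sham and 0.499% of old tumour cells, a tumour to sham ratio of 7.61 in young (6.07 to 9.65) and 0.669 in old mice (0.455 to 0.977), the latter within the 1.5-fold bound. The monocyte-like cluster was led by the MHC class II genes H2-Eb1, H2-Ab1 and H2-Aa and by Cd74, Plac8 and Cxcl9. The T cell-like cluster was led by Nkg7, a gene shared with natural killer cells, and by Cd3g and Trbc2. The size of the monocyte-like class depended on the clustering, and its young tumour share was 1.84% at Leiden resolution 2 and 2.02% under a stricter cell filter. Its make-up also differed: the summed CPM of microglia markers in this class was 3750 in young sham, 19947 in young tumour, 4062 in old sham and 3913 in old tumour, and that of monocyte markers 5598, 2312, 3859 and 4507. The 1 cluster named dendritic cell-like, led by Ccr7, Ccl22 and Il12b, was found in young tumour alone. It held 79 cells or 0.755% (0.598 to 0.940%), at least 26.6 times the floor of 3 cells in young sham. Dendritic cell markers were also counted in the monocyte-like class of every library. They summed to 657.3 CPM in young sham, 285.5 in young tumour, 829.9 in old sham and 959 in old tumour. Dendritic cells outside the named cluster are thus not excluded in any library. Neutrophil-like cells, led by S100a9 and S100a8, fell from 1.17% to 0.468% with the tumour in young mice and rose from 0.241% to 0.610% in old mice.

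**Figure D1:**
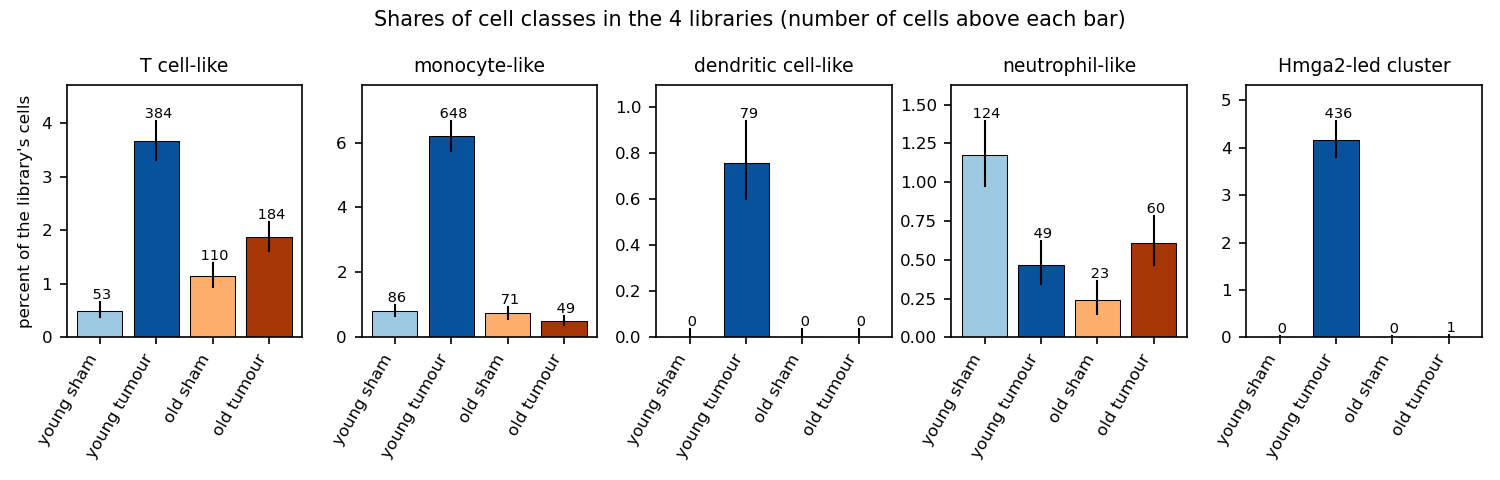
Shares of 4 immune cell classes and of the Hmga2-led cluster, in percent of the cells of each library, with exact 95% binomial intervals as black lines and cell numbers above the bars. The young tumour library has the highest share of T cell-like (3.67%), monocyte-like (6.19%) and dendritic cell-like (0.755%) cells and of the Hmga2-led cluster (4.17%).

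The larger resident classes differed less with the tumour than T cell-like and monocyte-like cells did in young mice. Smaller ones did not all do so. Oligodendrocyte precursor-like cells had tumour to sham ratios of 0.284 in young (0.178 to 0.439) and 0.0987 in old mice (0.0672 to 0.141). Olfactory ensheathing cell-like cells, absent from both sham libraries, were at least 17.5 and 26.2 times the floor of 3 cells. Whether the same tissue was taken for each library was not tested. Microglia-like cells were 35.1% of young sham, 27.9% of young tumour, 26.7% of old sham and 24.9% of old tumour cells, and astrocyte-like cells were 23.9%, 18.1%, 19.1% and 20.1% in the same order. Oligodendrocyte-like cells were 7.15% of young sham and 19.1% of old sham, a ratio of 2.67 (2.45 to 2.91), against 9.46% and 11.8% in young and old tumour, a ratio of 1.25 (1.15 to 1.36). An unnamed cluster led by Klk6, with oligodendrocyte markers, held another 1.94%, 2.22%, 6.31% and 5.62% of cells in young sham, young tumour, old sham and old tumour. Choroid plexus epithelium-like cells were 5.82% of young sham, 2.76% of young tumour, 5.85% of old sham and 9.41% of old tumour.

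One cluster of 437 cells came almost wholly from the young tumour library, with 436 cells there (4.17% of cells, 3.79 to 4.57%) and 1 cell in old tumour (0.0102%). Neither sham library held any, against floors of 3 cells of 0.0284% (young) and 0.0315% (old). The cluster was led by Hmga2 (ENSMUSG00000056758, GRCm38 chromosome 10, 120361275 to 120476469), a chromatin protein gene of embryonic and tumour cells, together with Xist, Lgals1, Col3a1 and Top2a. Its cells carried a median of 25664 UMIs, held 20.4% of the UMIs of the kept cells of the library and had a median doublet score of 0.0568, against 0.0355 in the library. Xist, transcribed from the inactive X chromosome, was found in 96.1% of them (93.8 to 97.7%), against 0.299% of the other cells of that library, which had a median of 3667 UMIs. UMIs of 4 Y-linked genes were found in 7.34% of the cluster (5.07 to 10.2%) and in 52.1% of the other cells. The cell cycle gene Mki67 was found in 69.5% of the cluster and in 0.265% of the astrocyte-like cells of the same library (median 3011 UMIs), and Cd44, a receptor gene for hyaluronan, in 87.4% and 2.01%. The cluster is confounded with its library and was given no name. Since it was nearly absent from old tumour, differences between the ages with a tumour cannot be told apart from its presence in young tumour. This holds for the immune cell shares above and for the interferon, MHC class I, MHC class II and T cell genes below.

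Old and young mice were compared within microglia-like cells, the largest class, to ask how the resident immune cells of the brain differ with age. Genes of inflammatory signalling were higher in old mice, with and without a tumour. Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007), a cytokine gene, was at 61.5 CPM (UMIs scaled to a common class total) in young sham and 618.5 in old sham, a ratio of 10.1 (9.36 to 10.8), and at 28.3 and 154.1 in young and old tumour, a ratio of 5.44 (4.79 to 6.19). Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139) was 6.74 times higher in old sham and 4.28 times higher in old tumour. Ildr2 was 11.4 and 9.22 times higher, Crlf2, a cytokine receptor subunit gene, 4.41 and 3.71 times, and Naalad2 4.02 and 3.83 times. Rgs7bp, at ratios of 0.161 and 0.196, and Cpe, at 0.453 and 0.527, were lower in old mice. Cxcl2 was 14.1 and 76.5 times higher, the latter from 2 UMIs in young tumour (20.9 to 636.8), and 5 cells held at least 50.3% of its UMIs in each library. Over the fixed list of inflammatory cytokines and chemokines (19 measured genes), the median log2 ratio was 1.96 in sham (1.76 to 2.08) and 0.78 in tumour-bearing libraries (0.62 to 0.89). Different clusters were the largest of the class in the 2 sham libraries: a cluster led by Tnf, Ccl4 and Il1a held 47.7% of old sham and 3.80% of young sham microglia-like cells, and a cluster led by P2ry12 15.5% and 42.2%. Without the clusters led by Tnf and by Atf3, the list medians were 1.02 in sham and 0.00 in tumour-bearing libraries, an alternative chosen after seeing the data. The Tnf-led cluster is led by genes of the list, so lower medians without it follow in part from the choice of cells. The immediate early list in the same cells had a median of 0.34 for age in sham, within the bound, with 8 of 26 genes higher (Egr1 at 1022 CPM in young sham and 2321 in old sham) and 4 lower (Hspa1b at 267.3 and 47.5). Over all classes its old against young medians in sham lay above 0 in 11 of 11. Ccl3, Ccl4 and Atf3 of that list were also among the leading genes of the Tnf-led cluster. A difference in handling or dissociation between the libraries therefore cannot be told apart from age here.

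Genes of the disease-associated state of microglia were also higher in old sham, with a list median of 0.97 (0.44 to 1.26), against 0.42 (0.36 to 0.48) in tumour-bearing libraries. Spp1, a secreted matrix protein gene, was at 19.6 CPM in young sham and 252.8 in old sham, and Apoe, a lipid carrier gene, at 1534 and 4934. The median of homeostatic microglia genes was −0.38 in sham (−0.39 to −0.34), within the 1.5-fold bound, while P2ry12 was lower at a ratio of 0.642. The senescence and secretory list had medians of 0.98 in sham and 0.73 in tumour-bearing libraries, with 5 of 9 measured genes higher in each.

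Tumour and sham libraries were then compared within microglia-like cells, to ask how a tumour in the other side of the brain changes them at each age. Immediate early genes, which respond within minutes to stimulation and to tissue dissociation, were lower in the tumour libraries at both ages. Klf4 (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466) was at a tumour to sham ratio of 0.172 in young (0.144 to 0.204) and 0.172 in old mice (0.150 to 0.197), and Atf3 at 0.291 and 0.273. The list median of 26 genes was −0.96 in young (−0.99 to −0.94) and −0.96 in old mice (−0.99 to −0.93), and 24 and 19 of the genes were lower. Tumour and sham libraries held these cells in different clusters: the Atf3-led cluster was 31.8% of young sham and 12.4% of young tumour microglia-like cells, the Tnf-led cluster 47.7% of old sham and 9.58% of old tumour, and the P2ry12-led cluster 15.5% and 45.6%. Without the clusters led by Atf3 and Tnf, the medians were −0.0517 and −0.50, and in those led by Tmem119 and P2ry12 alone −0.16 and −0.52, all within the bound. The Atf3-led cluster is itself led by genes of the list, so leaving it out takes away cells grouped by high values of these genes. Medians nearer to no change follow in part from that choice. The list also differed between the sham libraries, with medians above 0 for old against young in 11 of 11 classes, of which 4 were past the bound (lowest 0.10). Hspa1b, a heat shock gene, was at a ratio of 0.233 in young and 1.23 in old mice.

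Some of the MHC class II genes, which present antigen to T cells, were higher in tumour libraries, with larger ratios in young mice for those named here. In microglia-like cells H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823) rose from 7.27 to 291.5 CPM in young, a ratio of 40.1 (32.8 to 49.6), and from 10.3 to 38.1 in old mice, a ratio of 3.69 (3.03 to 4.51). In both sham libraries few cells carried it, since 5 cells held 61.2% (young) and 69.2% (old) of its UMIs. Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), the class II chaperone gene, rose 19.9 times in young (18.4 to 21.5) and 1.89 times in old mice (1.77 to 2.02). Cd74 was higher in oligodendrocyte-like cells of young tumour too, at 44.2 CPM against 2.62 in young sham, beside 1038 and 52.2 in microglia-like cells. Over 13 classes its lowest value was 24.7 CPM in young tumour and 0 in young sham, and its median 44.2 and 4.39. The oligodendrocyte-like value thus lay at the level of most classes, and whether this was free RNA was not tested. The median over the 8 measured microglia genes of the list was 2.32 in young (2.24 to 2.38) and 0.62 in old mice (0.57 to 0.68), with 4 genes higher in each. In the clusters led by Tmem119 and P2ry12 alone the young median was 1.31. Lgals3 was 3.77 times higher in young and 2.26 times in old mice, but its young log2 ratio was −0.16 without doublet removal and −0.00 at Leiden resolution 2. Mcpt2 was absent from both sham libraries, and 5 cells held 95.2% of its UMIs in young tumour.

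**Figure D2:**
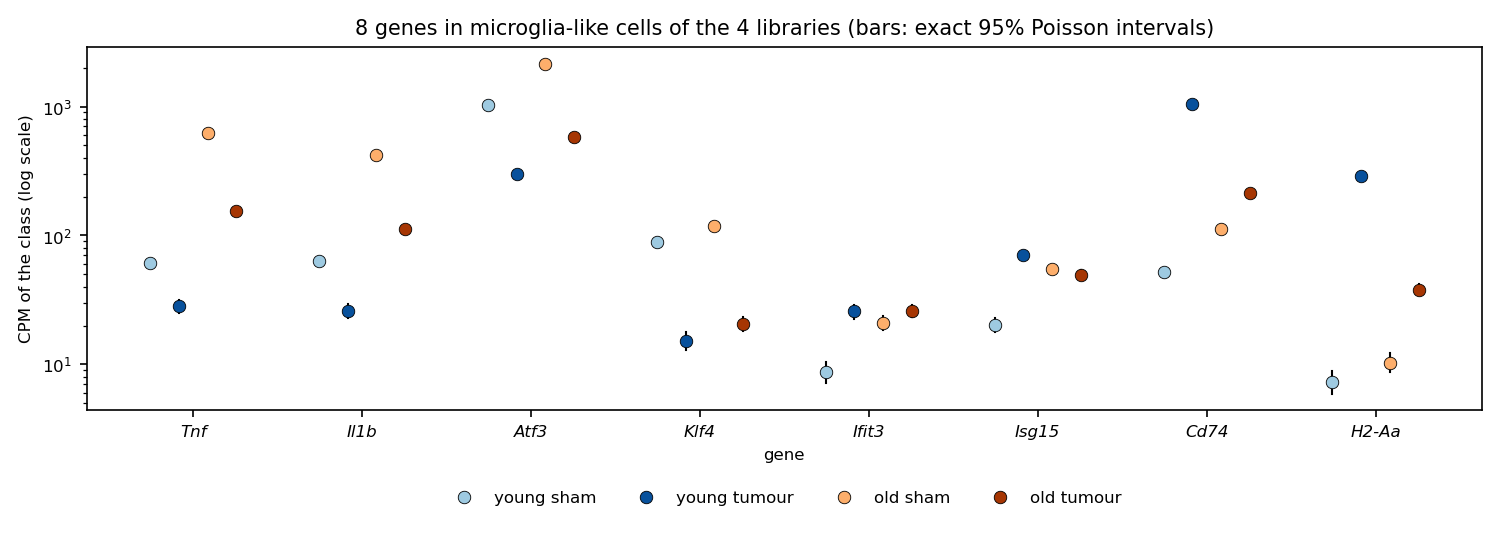
CPM of 8 genes in microglia-like cells, on a log scale, in the 4 libraries, with exact 95% Poisson intervals as black lines. Tnf runs from 28.3 in young tumour to 618.5 in old sham, while H2-Aa runs from 7.27 in young sham to 291.5 in young tumour.

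Interferon response genes separated young sham from the other 3 libraries in microglia-like cells. Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818) was at 20.2 CPM in young sham, 70.9 in young tumour, 55.3 in old sham and 49.5 in old tumour, and Ifi27l2a at 25.6, 178.6, 83.0 and 147.0. The list median of 22 genes was 1.36 for old against young in sham (1.19 to 1.43) and 1.56 for tumour against sham in young mice (1.39 to 1.74). It was −0.16 for old against young in tumour-bearing libraries (−0.24 to −0.05) and 0.18 for tumour against sham in old mice (0.09 to 0.26). The old ratio divided by the young ratio had a median log2 value of −1.72 (−1.8 to −1.44), with 17 of 22 genes lower. These values depended on the cells taken as microglia-like: the young tumour to sham median was 0.60 without doublet removal, 0.65 at Leiden resolution 2 and 0.48 in the clusters led by Tmem119 and P2ry12. In those clusters the old against young median in sham was 0.43 and the difference between the ages −0.44, so that all 3 lay within the bound. Markers of other cells moved too: from young sham to young tumour, the summed CPM in microglia-like cells went from 298.7 to 1682 for erythroid, 16.4 to 35.6 for monocyte, 1.63 to 10.4 for T cell and 0.297 to 3.52 for NK cell markers. H2-Q7 (ENSMUSG00000060550, chromosome 17, 35439155 to 35443773), an MHC class I gene, was 18.6 times higher in young tumour than young sham (15.3 to 22.9), against 1.37 times in old mice (1.20 to 1.57). C4b, a complement gene, was at 1.78, 47.3, 3.58 and 3.53 CPM in young sham, young tumour, old sham and old tumour. Cxcl9, a chemokine gene induced by interferon gamma, was at 0.815, 24.2, 13.4 and 3.28 CPM, with at least 61.0% of its UMIs in 5 cells of each library.

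Interferon genes set young sham apart by more at the ventricles, in choroid plexus epithelium-like and ependymal cell-like cells. In choroid plexus epithelium-like cells, Ifit1 (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009) was at 0.545 CPM in young sham, 28.4 in young tumour, 91.2 in old sham and 48.0 in old tumour. Its young sham value rests on 3 UMIs, and its young tumour to sham ratio was 52.1 (17.3 to 257.1). The choroid plexus epithelium interferon median of 14 genes was 3.86 for old against young in sham (3.49 to 4.25) and 2.98 for tumour against sham in young mice (2.47 to 3.15), while old tumour was below old sham at −0.87 (−0.95 to −0.79). In ependymal cell-like cells the tumour to sham interferon median was 3.38 in young (3.16 to 3.69) and 0.70 in old mice (0.56 to 0.79), and in young mice MHC class I genes rose further. H2-K1 (ENSMUSG00000061232, chromosome 17, 33996017 to 34000347) went from 116.7 to 2138 CPM in young mice, 18.3 times higher (16.1 to 20.9), and from 405 to 660.2 in old mice. B2m (ENSMUSG00000060802, chromosome 2, 122147686 to 122153083), the invariant light chain gene, went from 29.3 to 692.7 CPM in young and from 135.2 to 197.2 in old mice. The ependymal cell MHC class I median was 4.17 in young (3.92 to 4.32), with 15 of 15 genes higher, and 0.55 in old mice (0.45 to 0.70). Between the tumour libraries, ependymal Ifit3 was higher in old mice (543.2 against 336.6 CPM), while Gbp2, also of the interferon list, was lower (86.4 against 359.9 CPM).

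Other classes ranged widely. For tumour against sham in young mice, the interferon list median was 2.20 in monocyte-like cells, a class with more microglia markers in young tumour, 1.40 in T cell-like, 1.00 in border-associated macrophage-like, 0.89 in fibroblast-like, 0.85 in oligodendrocyte-like and 0.44 in astrocyte-like cells, and −0.20 in endothelial cell-like (−0.28 to −0.16) and −0.17 in pericyte-like cells. In old mice the same medians were −0.01, −0.60, 0.46, −0.52, 0.26, 0.33, −0.10 and −0.20. Over the 11 classes measured, the difference between the ages lay below 0 in 11 for MHC class I and in 9 for interferon genes, and past the bound in 7 for each list.

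**Figure D3:**
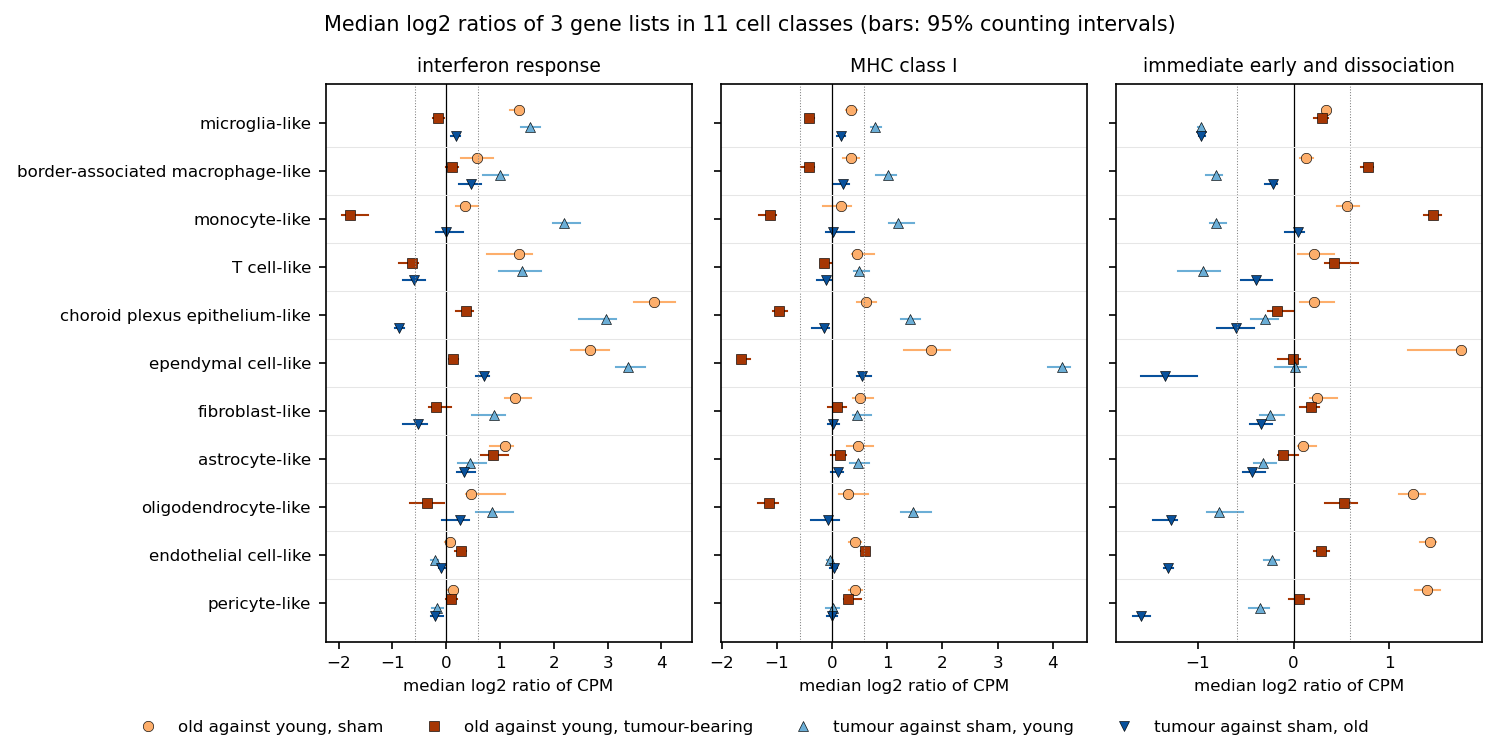
Median log2 ratios of the interferon response, MHC class I and immediate early lists in 11 cell classes (1 symbol per comparison) with 95% counting intervals as lines and dotted lines at 1.5-fold. Tumour against sham in young mice reaches 3.38 (interferon) and 4.17 (MHC class I) in ependymal cell-like cells, and immediate early medians of tumour against sham lie below 0 in 10 of 11 classes at each age.

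T cell-like cells were compared to ask which programmes they carried in each library. Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), the PD-1 receptor gene of activated and exhausted T cells, was at 8.77 CPM in young sham (2 UMIs), 179.0 in young tumour, 114.4 in old sham and 34.0 in old tumour. Its tumour to sham ratio was 20.4 in young (5.61 to 169.2) and 0.297 in old mice (0.178 to 0.488). Gzmb, a cytotoxic protease gene, was at 17.5, 551.9, 387.9 and 181.2 CPM, and Gzmk, another granzyme gene, at 48.2, 45.7, 258.6 and 219.0. The T cell exhaustion and regulation list had a median of 2.18 for tumour against sham in young (1.81 to 3.14) and −0.87 in old mice (−1.13 to −0.23), while the effector and residence list stayed within the bound at 0.53 and −0.24. In young sham, Foxp3 and Ctla4 of the exhaustion and regulation list had 0 UMIs, Lag3 1 and Tox 4. The young median thus joins bounds with values from few UMIs. Its interval gives a count of 0 no counting error. Cell cycle genes were lower in old mice, with list medians of −2.32 in sham and −1.90 in tumour-bearing libraries. Mki67 was at 149.1 CPM in young sham and 4.97 in old sham (2 UMIs), a ratio of 0.0333 (0.00388 to 0.130), and at 122.7 and 23.9 in young and old tumour. The young sham values come from 53 cells, and markers of other cells moved in this class: the summed CPM of NK cell markers was 877.1 in young sham, 1105 in young tumour, 668.9 in old sham and 479.5 in old tumour, and that of oligodendrocyte markers 1785, 809.5, 507.3 and 449.3. In monocyte-like cells, Isg15 was at 86.6 CPM in young sham, 699.2 in young tumour, 139.4 in old sham and 87.4 in old tumour, the last from 49 cells. Microglia markers rose in this class in young tumour as well (19947 against 3750 summed CPM in young sham), so the cells compared differ in kind.

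Astrocyte-like cells were compared for reactive genes. Gfap, the astrocyte filament gene, was at 75.7 CPM in young sham, 196.1 in young tumour, 140.9 in old sham and 200.9 in old tumour, and the complement gene C4b at 24.2, 47.5, 85.8 and 90.6. The pan-reactive astrocyte list had medians of 0.93 for age in sham (0.81 to 1.33), 0.39 for age in tumour-bearing libraries, 0.97 for the tumour in young mice (0.58 to 1.14) and 0.26 in old mice. The interferon list was higher in old astrocyte-like cells in sham (1.08, 0.81 to 1.24) and in tumour-bearing libraries (0.88, 0.65 to 1.16). Gpx8, a peroxidase gene of the endoplasmic reticulum, was lower in old mice, at ratios of 0.102 and 0.144, and Pde10a was 3.78 and 4.95 times higher with the tumour in young and old mice. Cxcl10, a chemokine gene of the interferon response, was at 0.325, 8.43, 7.73 and 39.1 CPM, with 3 UMIs in young sham and at least 66.2% of its UMIs in 5 cells of each library.

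Oligodendrocyte-like cells of old mice carried more Hopx (4.73 times in sham and 5.24 times in tumour-bearing libraries) and more Itgb5, an integrin gene (5.78 and 4.79 times). Itih3 (ENSMUSG00000006522, chromosome 14, 30908572 to 30923760), a matrix-binding protein gene, was lower at 0.166 (0.143 to 0.192) and 0.163 (0.136 to 0.196). C4b rose with age from 21.4 to 129.9 CPM in sham and from 42.8 to 162.7 in tumour-bearing libraries. The reactive oligodendrocyte list had medians of 0.60 for age in sham and 0.66 for the tumour in young mice, and of 0.12 for age in tumour-bearing libraries and for the tumour in old mice. Hmgcs1, a cholesterol synthesis gene, was lower in old mice (0.573 and 0.520), while the medians of the cholesterol list stayed within the bound (−0.38 and −0.57). Myelin genes in oligodendrocyte-like cells had medians from −0.26 to −0.05. The immediate early median was 1.25 for age in sham, and −0.77 and −1.27 for the tumour in young and old mice, with Fos at 152.5, 50.5, 966.5 and 196.5 CPM in young sham, young tumour, old sham and old tumour.

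Endothelial cell-like cells of old mice had more transcripts of 2 MHC class I genes. H2-Q6 was at 1.08 CPM in young sham and 62.2 in old sham, 57.5 times higher (27.6 to 144.4), and at 3.73 and 62.5 in tumour-bearing libraries, 16.7 times higher (10.5 to 28.5). H2-Q7 was 20.7 times (15.4 to 28.6) and 12.2 times higher (9.60 to 15.6), and Rasgrf2 6.74 and 6.51 times. The endothelial cell MHC class I medians were 0.41 in sham, within the bound, and 0.60 in tumour-bearing libraries, and −0.03 and 0.04 for tumour against sham. The blood-brain barrier list had medians from −0.13 to 0.02, and the endothelial activation list 0.63 and 0.31 for age and 0.07 and −0.24 for the tumour. Vcam1, an adhesion receptor gene for leukocytes, was lower in both tumour libraries (ratios of 0.392 and 0.643). The immediate early median was 1.42 for old against young in sham and −1.31 for tumour against sham in old mice. Markers of other cells moved in this class: the summed CPM of oligodendrocyte markers was 774.3 in young sham, 898.4 in young tumour, 1584 in old sham and 1106 in old tumour, that of neuron markers 118.2, 115.7, 339.6 and 326.7, of erythroid markers 294.3, 1087, 600.2 and 34.2, and of astrocyte markers 1158, 497.4, 327.5 and 349.7.

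Class II genes moved with age in cells at the brain surface. In fibroblast-like cells, Cd74 was at 335.7 and 293.2 CPM in young sham and young tumour, and at 1477 and 1624 in old sham and old tumour. The fibroblast MHC class II median was 2.03 for age in sham (1.88 to 2.14) and 1.93 in tumour-bearing libraries (1.70 to 2.16), with 6 of 6 genes higher in each, and −0.00 and 0.13 for the tumour. The class joins 2 clusters in differing proportions, and its fibroblast markers summed to 3852 CPM in young sham, 7112 in young tumour, 2490 in old sham and 3500 in old tumour. In border-associated macrophage-like cells, the same list was lower in old mice (−0.63 and −0.67) and higher with the tumour at both ages (0.65 and 0.60). Markers of other cells moved in this class too, given here for young sham, young tumour, old sham and old tumour. Monocyte markers summed to 299.2, 302.2, 65.2 and 194.5 CPM, and dendritic cell markers to 333.2, 374.9, 839.1 and 796.1.

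Some genes moved alike over most classes. S100a9, a neutrophil gene, had a median over 13 classes of 15.6 CPM in young sham, 2.75 in young tumour, 3.52 in old sham and 9.83 in old tumour, and Avp, a neuropeptide gene of hypothalamic neurons, 2.42, 20.8, 0 and 1.13. In old sham Avp was at 340.9 CPM in neuron-like cells and at most 6.21 in any other class. Both ranked among the largest ratios in microglia-like cells, where S100a9 was at 22.5, 2.21, 4.43 and 10.9 CPM and Avp at 3.93, 31.4, 0.155 and 2.27.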

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

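In this part, the 4 tests of explanations were chosen only after the results were seen. The results below moved in opposite directions with the tumour in young and old mice, each past 1.5-fold at both ages. Each rests on 1 library per group, and the differences were not tested. Values are log2 of the old tumour to sham ratio divided by the young one.

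Among interferon genes of choroid plexus epithelium-like cells, Ifit1 differed by −6.63, Ifi27l2a by −6.15, Isg15 by −4.94 and Iigp1 by −4.78. The interferon list differed by −3.75 in this class (2.98 in young and −0.87 in old mice) and by −2.51 in T cell-like cells (1.40 and −0.60). The T cell exhaustion and regulation list differed by −2.89 (2.18 and −0.87), with Foxp3 and Ctla4 at 0 UMIs in young sham and other members at few. In microglia-like cells, the chemokine gene Cxcl9 differed by −6.92.

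Genes of other cells were among them. S100a9, a neutrophil gene, differed by 4.65 in microglia-like and 4.28 in astrocyte-like cells, and the neutrophil-like share by 2.66 (−1.32 in young and 1.34 in old mice). Cd74 differed by −4.43 in astrocyte-like cells, and the endothelial genes Flt1 and Cldn5 by 2.18 and 2.97 in choroid plexus epithelium-like cells, where Flt1 reversed to −0.22 with cells thinned to 1000 UMIs. The choroid plexus epithelium-like share differed by 1.76 (−1.07 and 0.69), and within this class AY036118 by 2.04 and Lars2 by 1.46. Both genes also moved in these directions by their medians over 13 classes. In young sham, young tumour, old sham and old tumour these were 628.5, 471.3, 281.4 and 694.9 CPM for AY036118. For Lars2 they were 498.4, 452.8, 298.9 and 531.9 CPM. Mid1 differed by 3.34 in microglia-like cells, Cdyl by −1.34 in astrocyte-like cells, Nppc by 1.81 in oligodendrocyte-like cells, and Cytl1 by 5.37 and Bgn by 2.22 in endothelial cell-like cells, where Bgn reversed to −0.20 under the stricter cell filter.

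The lower tumour to sham ratio of interferon genes in old mice was weighed against 3 explanations. Free RNA from immune cells of the young tumour library would raise these genes in every class, but the larger of the rises in oligodendrocyte-like and endothelial cell-like cells was 4.68% of the smaller of the rises in choroid plexus epithelium-like and ependymal cell-like cells, which argues against it as the whole cause (the list median in oligodendrocyte-like cells was 0.85, and free RNA stays open there). A high level in the old sham library, or a low one in young sham, may account for part of the difference, but its test could not decide this. For each gene, the difference is also the old to young ratio with a tumour divided by that in sham. The old to young medians therefore restate the difference and show only between which libraries it lies. They were taken in microglia-like, choroid plexus epithelium-like and ependymal cell-like cells. There the old to young list median was past 1.5-fold in sham, and its value farthest from 0 in tumour-bearing libraries was 0.38. In ependymal cell-like cells the median between the tumour libraries joins opposite genes. Zbp1 (ratio 0.216), Gbp2 (0.240) and Stat2 (0.416) were lower in old tumour, while Ifi27l2a (2.96) and Ifit3 (1.61) were higher. A sham level alone leaves the lower genes unaccounted for. Other classes stay open: between the tumour libraries the old to young median was −1.79 in monocyte-like cells, whose make-up differed, −0.64 in T cell-like and 0.88 in astrocyte-like cells, and an effect of age was not tested. Fewer tumour cells in the old tumour library cannot be told apart from age with 2 tumour libraries. The Hmga2-led cluster was 0.0102% of cells there, but its source stays open, so its share is not a measure of tumour cells.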

How the results depend on the processing

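Settings described as later were chosen after seeing the data. Those that leave out the Atf3- and Tnf-led clusters take away cells grouped by genes of the immediate early and inflammatory lists, so smaller medians of these lists follow in part from the choice. With no replicates, a value counts as unchanged when it stays within its 95% counting interval, and as reversed only when a value past 1.5-fold changes sign. Smaller values that change sign count as moved or unchanged. Of 1536 list medians under an alternative (165 results), 1100 were unchanged, 435 moved and 1 reversed. Of 2029 values of named genes (290 results), 1694 were unchanged, 315 moved and 20 reversed. Of 312 shares, 221 were unchanged, 91 moved and 0 reversed. Among list medians past 1.5-fold, 625 of 716 stayed past it. No paired analysis was possible because each group has 1 library. For the values below, the cause was not tested.

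The monocyte-like share of young tumour (6.19%) was 2.02% under the stricter cell filter and 1.84% at Leiden resolution 2, and the Hmga2-led cluster (4.17%) was 4.65% without doublet removal and 4.70% under the stricter filter.

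In microglia-like cells, the young tumour to sham interferon median (1.56) was 0.60 without doublet removal, 0.65 at resolution 2, 1.22 for the mean of each cell's CPM, 0.96 with cells thinned, 1.27 for members with at least 50 CPM, and, later, 2.07 without the clusters led by Atf3 and Tnf and 0.48 in those led by Tmem119 and P2ry12. The old median (0.18) was 0.0498, 0.0413, 0.0580 and −0.0562 under the first 4 of these settings and −0.0649 without the Atf3- and Tnf-led clusters. The difference between the ages (−1.72) was −0.67, −0.73, −1.17, −1.12, −1.43, −2.30 and −0.44 in the order of the 7 settings. The old to young median in sham (1.36) was 0.43 in the Tmem119- and P2ry12-led clusters. In choroid plexus epithelium-like cells the difference (−3.75) was −4.15 under the stricter filter, −4.19 for the mean of each cell's CPM and −3.10 for members with 1 UMI in each library.

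The microglia MHC class II median in young mice (2.32) was 1.39 without doublet removal, 2.18 under the stricter filter, 1.68 at resolution 2, 1.58 for the mean of each cell's CPM, 1.66 thinned, 4.32 for members with at least 50 CPM and 1.31 in the Tmem119- and P2ry12-led clusters. The inflammatory median for age (1.96 in sham) was 1.75 for members with at least 50 CPM, 1.02 without the Atf3- and Tnf-led clusters and 0.92 in those led by Tmem119 and P2ry12. In tumour-bearing libraries (0.78) it was 1.00 without doublet removal, 1.00 at resolution 2, 0.93 thinned, 0.000305 without the Atf3- and Tnf-led clusters and 0.15 in those led by Tmem119 and P2ry12. The tumour to sham median of the inflammatory list in young mice, lower past 1.5-fold in the main setting, reversed to 0.52 without the Atf3- and Tnf-led clusters.

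The immediate early median in young mice (−0.96) was −0.92 without doublet removal, −0.92 at resolution 2, −0.94 for the mean of each cell's CPM, −0.91 thinned, −0.93 without mitochondrial and ribosomal protein genes, −0.0517 without the Atf3- and Tnf-led clusters and −0.16 in those led by Tmem119 and P2ry12. In old mice (−0.96) it was −1.03 for the mean of each cell's CPM, −1.01 thinned, −0.50 and −0.52.

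Reversed log2 ratios without doublet removal were Fcer1g in astrocyte-like cells, old against young with a tumour (0.0530), the difference between the ages of Cxcl10 in astrocyte-like (0.00233) and of Ermn in endothelial cell-like cells (0.0233), Cxcl10 in endothelial cell-like cells, old against young with a tumour (−1.89), and Lgals3 in microglia-like cells of young mice (−0.16, and −0.00111 at resolution 2). Thinning to 1000 UMIs reversed Avp in old astrocyte-like (−0.18) and old endothelial cell-like cells (−1.15) and in the latter class for age in sham (1.22), the differences between the ages of Flt1 in choroid plexus epithelium-like (−0.22), Opalin in endothelial cell-like (0.30) and Cxcl2 in microglia-like cells (−0.10), and, in young choroid plexus epithelium-like cells, Cidea (−1.65, and −0.10 for the mean of each cell's CPM), Junb (0.16) and Kpna3 (0.48). The stricter filter reversed Leng8 (−0.44) and Slc1a2 (0.0218) in choroid plexus epithelium-like cells, and Cd74 (−0.0438) and the difference of Bgn (−0.20) in endothelial cell-like cells. Thinning left out 227, 172, 86 and 82 microglia-like cells of young sham, young tumour, old sham and old tumour.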

Other observations

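In this part, the 6 tests of explanations were chosen only after the results were seen. Oligodendrocyte precursor-like cells were 0.908% of young sham, 0.258% of young tumour, 3.51% of old sham and 0.346% of old tumour cells. Olfactory ensheathing cell-like cells were 0.497% of young tumour and 0.824% of old tumour cells and absent from both sham libraries. Both classes thus differed between tumour and sham libraries at each age. A difference in the tissue taken or in the cells recovered was not tested. It cannot be told apart from the tumour in any tumour to sham comparison here. Neuroblast-like cells were 1.27%, 2.60%, 1.03% and 1.09% of cells in young sham, young tumour, old sham and old tumour. Fam155a had 10, 19, 3473 and 6 UMIs in oligodendrocyte-like cells of the same libraries. In old sham, 773 of 1817 of these cells (42.5%) held none of it, against 358.1 if its UMIs were spread evenly.

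For the cells of the Hmga2-led cluster, 3 sources were weighed. Doublets of host cells would carry Y-linked genes, but these were found in 7.34% of the cluster, against 52.1% of the other cells. A female mouse behind the library would bring Xist to many cell types, but Xist was found in 0.299% of the other cells. Injected tumour cells stay open: the cluster was absent from both sham libraries (exact upper limit 0.0387% in old sham), but that absence is what singled it out and supports no source. Apart from that absence, Xist in 96.1% of the cluster and the few Y-linked UMIs set its cells apart from the library's other cells. These values argue against both host sources above, but injected cells were not tested directly. The reporter sequences of the injected line were not analysed here.

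The lower immediate early genes in both tumour libraries may come from a difference in handling or dissociation between the libraries: the list also differed between the sham libraries, with old against young medians above 0 in 11 of 11 classes, though past 1.5-fold in 4 of them. A change confined to microglia-like cells is argued against by the other classes, where 18 of 20 tumour to sham medians lay below 0 with their interval. That count takes any value below 0. With microglia-like cells included, 5 of 11 medians in young and 6 of 11 in old mice were lower past 1.5-fold. Classes within the bound weigh little here. Free RNA from microglia-like cells would lower the list by a like amount in every class, but in old mice the largest fall of the summed CPM among 7 other classes was 35.5 times the smallest, and in young mice it rose by 788.5 in endothelial cell-like and by 219.7 in pericyte-like cells. A first form of this test, on the size of each fall relative to that in microglia-like cells, had decided nothing and was replaced after its result was seen, and free RNA stays open for small falls such as that of astrocyte-like cells (1.53% of the microglia fall). Handling is confounded with the groups, and an effect of the tumour or of age was not tested apart from it.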
